A study of Mus musculus with 6 samples.

How the data were processed

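Gene expression was measured by RNA sequencing in whole hearts of 6 mouse pups at postnatal day 14, on a mixed ICR and C57BL/6 background. Per the labels' protocols, hearts were flash frozen, RNA was extracted with Trizol, and libraries were made from total RNA with the Illumina TruSeq RNA kit, version 2, a kit that does not mark the strand of the RNA. All 6 libraries carry the same sequencing run identifier, so the groups were not sequenced in separate runs. Batches of RNA extraction or library preparation cannot be checked from the labels. The control group held 3 pups with the Cre-dependent receptor allele and no Cre, and the mutant group held 3 littermates that also carried Myh6-Cre. Groups and replicate numbers were taken from the sample titles.

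For each heart there was a table of counts and a table of RPKM values. The deposited counts are whole numbers per Ensembl gene, and per the submitters' processing notes cutadapt 1.9, STAR 2.5.2b, featureCounts 1.5.1 and the mm10 build were used, with no role or order given. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The deposited RPKM values, made by the authors, are counts divided by a gene length and a library total. Across genes, the ratio of count to RPKM between libraries was constant within a relative spread of 8.14e-07, and the total that the RPKM values imply was 0.9999 to 1.0011 times the sum of the deposited counts. RPKM therefore holds no correction for the composition of a library. The implied gene length had a median of 1.006 times the summed exon length in GENCODE release M21, which uses the same genome build.

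The tables list 20121 genes, each with at least 2 counts over the 6 libraries, so genes without counts had been left out. Symbols, coordinates and exon overlaps were taken from GENCODE M21 by gene identifier, which matched 20081 identifiers and left 40 without a name. Of the listed genes, 16627 are annotated as protein coding.

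Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr at its defaults, which left 14877 genes and removed 5244. Libraries were scaled with TMM. The quasi-likelihood F test compared mutant with control hearts with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05, with no fold threshold. Fold changes are mutant over control, CPM values are counts divided by the TMM-scaled library size, the usual unit of edgeR, and errors on CPM are SD over 3 hearts. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic, which is an approximation. On simulated counts for this comparison, with 200 of 14777 genes changed, the test recovered 56% of the changes of 1.5-fold, 84% of those of 2-fold, and 100% of those of 4-fold and of 8-fold. It made 184 calls there, of which 7.61% were false. Far fewer genes changed there than the 37.5% called in the hearts, and with random signs, so these rates may not carry over.

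In all, 35 gene lists of pathways, cell types and sample quality were fixed before the data were examined, as were the main test, the rule for naming genes and all alternatives but 1. Lists with at least 3 tested members were compared with the other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 32 lists. Camera with a correlation estimated for each list and the rotation test fry were run as alternatives. Members past the threshold were counted over all genes tested and again with p-values adjusted over the list alone. Several lists share members, so their results are not independent.

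The genes named were 10 fixed genes (Thra, Thrb, Myh6, Myh7, Atp2a2, Pln, Hcn2, Nppa, Nppb and Mki67), the 10 genes with the largest rise and the 10 with the largest fall, and members of each list. The largest changes were taken among called genes with a mean CPM of at least 1 and no overlap between groups, passing over predicted or unnamed gene models. From each list, up to 4 called members with the smallest adjusted p were taken, or, where none was called, the 2 with the highest mean CPM. This gave 128 genes, of which some are not reported here. Further genes named as the exceptions in a list were chosen after their values were seen.

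The depth was 43314706 to 62095277 counts per library. A few genes had 3 counts or fewer in a library, and for these the ratio of summed counts, scaled by effective library size, is given with an exact 95% interval that covers counting error only. Where exons of a gene overlap those of a gene on the opposite strand, reads of the pair cannot be told apart with this kit. The overlap is given as a percentage of exon bases for some genes only. Others named below also have one, such as Gnas (22%), Prdx5 (19.1%), Gadd45a (19.1%), Tceal7 (18.3%), Ckm (15.5%) and Csf1r (15.1%). Globin genes, the heat shock genes Hspa1a and Hspa1b and the tubulin genes have near-identical copies between which reads may be split, so their values are uncertain.

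The alternatives were DESeq2 size factors or upper-quartile scaling in edgeR, leaving out genes of the mitochondrial genome, DESeq2 1.42.0, limma-voom, no filter or a filter at a CPM of 1 in 3 libraries, an adjusted p under 0.01, glmTreat against a 1.5-fold change and the replicate number as a block. The deposited RPKM values were tested with limma on log2(RPKM + 1) and log2(RPKM + 0.1) for genes with a mean RPKM of at least 0.5, and on log2(RPKM + 1) without that filter. Fold changes on these scales understate the change of low genes. Each library was left out in turn. Offsets for GC content and exon length were added after the data had been seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for joining tables and drawing.

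Libraries of the same group were compared before averaging. Their counts differed by 10.6 to 29.8 times the sampling noise (chi-square per degree of freedom), so none was a repeat of another.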

Results

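Hearts were collected from mouse pups at postnatal day 14 and their RNA was sequenced. The mutant pups carried Myh6-Cre, which is active in heart muscle cells, and a knock-in allele from which Cre switches on a dominant negative form of thyroid hormone receptor alpha, the nuclear receptor encoded by Thra. The control pups were littermates with the allele and no Cre. There were 3 hearts in each group, each from a separate pup. The comparison asks which genes of the heart change when the altered receptor is switched on in heart muscle cells. No group carried Myh6-Cre without the allele, so effects of Cre itself cannot be told apart from those of the receptor. The control libraries held 43314706, 62095277 and 54354873 counts and the mutant libraries 46867237, 45944049 and 48359735. The p-values measure the spread between these 6 hearts only.

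The groups differed more than the hearts within them. The first principal component held 73.9% of the variance and separated control from mutant hearts. Correlations of log2 CPM across genes were 0.992 to 0.995 for pairs within a group and 0.970 to 0.974 for pairs across groups. Transcripts of the mitochondrial genome took 24.0% ± 1.41 (SD, n = 3) of the counts in control hearts and 17.8% ± 1.01 (SD, n = 3) in mutant hearts. The 10 most counted genes took 28.5% ± 1.12 in control and 20.9% ± 0.768 in mutant hearts (SD, n = 3 each).

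Of the 14877 genes tested, 2688 were higher and 2898 lower in mutant hearts by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, together 37.5%. Of these, 666 were higher and 452 lower by at least 2-fold. Over all genes tested, the CPM values of the groups did not overlap for 49.8%, where chance gives 10% for 3 hearts against 3. These calls are relative to the median gene, which TMM scaling holds at -0.00 on the log2 scale. The deposited RPKM values have no such scaling, and on log2(RPKM + 1) limma called 6595 genes higher and 1083 lower, 85.9% of the calls being higher against 48.1% with TMM. The median of all genes was then shifted by 0.21, and by 0.27 on log2(RPKM + 0.1), so small decreases in particular depend on the scaling. On log2(RPKM + 0.1), 6584 of 12357 genes were higher and 1077 lower. Medians and counts of list members on that scale, given below, are to be read against these values.

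The receptor genes moved in opposite directions. Thra (ENSMUSG00000058756, mm10 chromosome 11, 98740638 to 98769006, plus strand) rose from 76.7 ± 8.54 to 137 ± 10.4 CPM (SD, n = 3 each), a log2 fold change of 0.83 ± 0.09 (SE), with an edgeR quasi-likelihood adjusted p of 1.01e-04 after Benjamini-Hochberg. Its exons overlap those of Nr1d1 on the opposite strand over 5.7% of their bases, and Nr1d1 had a log2 fold change of 0.11 (adjusted p = 0.775 in the same edgeR test). Counts per gene do not tell the altered from the normal Thra transcript, so this value is a weak check of the genotype labels. Thrb, which encodes the other nuclear receptor for the hormone, fell 5.92-fold, from 34.5 CPM to 5.82 ± 0.274 CPM (SD, n = 3). Rxrg, a partner receptor, fell 3.74-fold. Dio2, the deiodinase that makes active hormone, rose 3.47-fold from a low level of 1.44 CPM. Of the 15 measured genes for receptors, cofactors, transporters and deiodinases, 3 rose, 5 fell and 7 did not pass the test, and 3 and 6 passed when adjusted over the list alone. The list as a whole was not shifted (camera adjusted p = 0.754), and 3 were lower without control replicate 2. Its median log2 fold change was 0.03, while its mean, -0.20, and camera's direction were negative, and on log2(RPKM + 0.1) the median was 0.34, with 9 higher and 2 lower. Without mutant replicate 2 the median turned to -0.00. Fry, which asks only whether the members move one way on balance, gave an adjusted p of 0.0109.

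Genes that thyroid hormone is known to raise in heart muscle were mostly lower in mutant hearts. Myh6, the fast myosin heavy chain of adult mouse heart (ENSMUSG00000040752, chromosome 14, 54941921 to 54966927, minus strand), fell from 37265 ± 1938 to 3830 ± 431 CPM (SD, n = 3 each), a log2 fold change of -3.28 ± 0.10 (SE). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell 3.35-fold to 4142 ± 80.3 CPM, the pacemaker channel gene Hcn2 fell 17.1-fold, and the potassium channel gene Kcnd2 fell 13.6-fold. Each of these had an edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) of 2.79e-07 or less. Of the 19 measured genes of this list, 14 fell, 1 rose (the calcium channel gene Cacna1c) and 4 did not pass, with the same numbers when adjusted over the list alone. The median log2 fold change was -1.09 (camera adjusted p = 2.87e-07, and adjusted p = 0.141 with an estimated correlation).

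Genes that the hormone is known to lower were mostly higher. Myh7, the slow myosin heavy chain of the fetal heart (ENSMUSG00000053093, chromosome 14, 54970684 to 54994626, minus strand), rose from 319 ± 60.6 to 18083 ± 922 CPM (SD, n = 3 each), a log2 fold change of 5.83 ± 0.15 (SE). Myh7 took 0.0288% ± 0.0054 (SD, n = 3) of all counts in control hearts and 1.84% to 2.10% in the mutant hearts. Myh6 took 3.38% ± 0.179 in control and 0.423% ± 0.054 in mutant hearts (SD, n = 3 each). Adcy5, an adenylyl cyclase, rose 1.64-fold. Of the 8 members, 6 rose and 2 fell, and the counts were the same when adjusted over the list alone. Thra is among the 6, and since it is the altered gene, its rise may not reflect hormone signalling. The members that fell were the potassium channel gene Kcnk3, by 0.85 on the log2 scale, and Pln, which encodes phospholamban, the inhibitor of the Atp2a2 pump, by 0.35. The exons of Pln overlap a gene on the opposite strand over 64.7% of their bases, and its call was lost on the RPKM scales. The median of the list was 0.77 (camera adjusted p = 0.0171, and adjusted p = 0.265 with an estimated correlation).

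**Figure D1:**
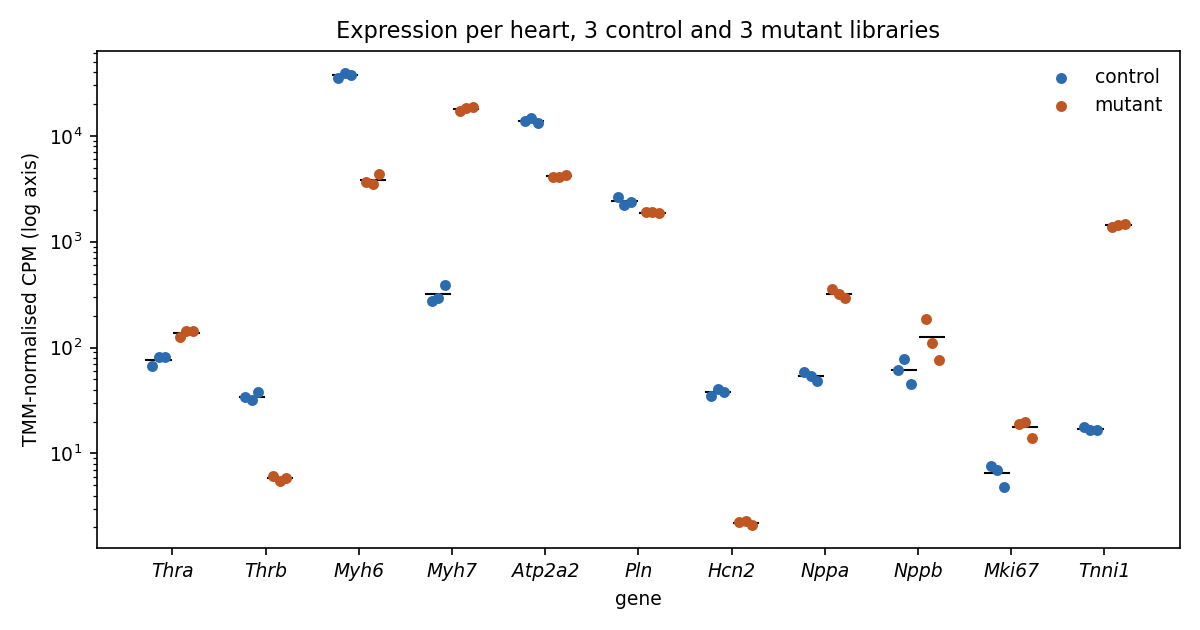
Expression of 11 named genes in each heart, as TMM-normalised CPM on a log axis. Each point is 1 of 3 control (blue) or 3 mutant (orange) hearts and black lines are means; Myh6 lies at 37265 CPM in control and 3830 in mutant hearts on average, Myh7 at 319 and 18083, and the groups overlap for Nppb alone among these genes.

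Among genes with a mean CPM of at least 1, the largest rises were those of Tnni1, the slow skeletal troponin I of the immature heart, and of Myh7. Tnni1 rose 83.9-fold, from 17.0 ± 0.735 to 1426 ± 48.8 CPM (SD, n = 3 each), with the smallest adjusted p of all genes in edgeR's quasi-likelihood test (1.96e-10, Benjamini-Hochberg). Next came the cadherin gene Cdh3, the relaxin receptor gene Rxfp1 (32.7-fold), Plppr1, the keratin gene Krt18 (22.0-fold), Insc, Tceal7, the collagen prolyl hydroxylase subunit gene P4ha3 and the tubulin gene Tubb2b (12.4-fold). Control hearts held few counts of Cdh3 (10 in all, against 420 in mutant hearts, a ratio of 39.0 with a 95% interval of 21.002 to 81.9) and of Plppr1 (16 against 464, a ratio of 26.9 with an interval of 16.4 to 47.5).

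The largest fall with the same CPM limit was that of Lrtm1, which went from 334 ± 24.5 to 1.93 ± 0.835 CPM (SD, n = 3 each), 174-fold lower. Foxo6os, a gene on the plus strand of chromosome 4 next to Foxo6 on the minus strand, went from 1014 counts to 8 over 3 hearts each (136-fold, with an interval of 69.0 to 317), and Rp1 from 697 to 10 (75.0-fold, with an interval of 40.6 to 157). Art1, an ADP-ribosyltransferase gene whose exons overlap Chrna10 on the opposite strand over 36.5% of their bases, fell 70.8-fold. The channel genes Cngb3 and Scn4a fell 47.1-fold and 29.9-fold, the lipid enzyme gene Pnpla3 42.8-fold, Hrasls 25.3-fold and Ush1c 22.6-fold. In each direction 1 unnamed gene model with a change of this size was passed over.

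More fetal genes of heart muscle rose than fell, and most genes of mature heart muscle fell. Of 19 measured fetal genes, 11 rose, 1 fell and 7 did not pass the test, or 12, 2 and 5 when adjusted over the list alone. Besides Tnni1 and Myh7, the atrial natriuretic peptide gene Nppa rose 6.01-fold, to 322 ± 29.7 CPM (SD, n = 3), and the stress-responsive gene Ankrd1 rose by 1.93 on the log2 scale. Nppa shares 61.5% of its exon bases with a gene on the opposite strand. Nppb, the brain natriuretic peptide gene, rose 2.04-fold with overlapping groups (edgeR quasi-likelihood adjusted p = 0.0220, Benjamini-Hochberg). That call was lost with DESeq2 (adjusted p = 0.0578), without control replicate 1 (0.0640) and without control replicate 3 (0.0540). The member that fell was Tnnt1, slow skeletal troponin T. The median of the fetal list was 0.49 (camera adjusted p = 4.05e-04, and adjusted p = 0.265 with an estimated correlation).

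Of 27 measured genes of mature heart muscle, 21 fell, 1 rose (Cacna1c) and 5 did not pass, with the same numbers adjusted over the list alone. Myoz2, a protein of the Z-disc, fell 3.25-fold, the cytochrome oxidase subunit gene Cox7a1 3.18-fold, and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 1.58 on the log2 scale. Tnni3, the adult cardiac troponin I, fell by 1.27 on the log2 scale. The median was -0.77 (camera adjusted p = 5.01e-10, and adjusted p = 0.265 with an estimated correlation). Over all 32 measured sarcomere genes there was no common direction, with 5 higher, 12 lower and 15 not past the threshold, counts that were equal when adjusted over the list alone (camera adjusted p = 0.314). The median of the sarcomere list was -0.06, its mean 0.08 and its camera direction negative, while fry's direction was positive, and on log2(RPKM + 0.1) its median was 0.23, with 14 higher and 8 lower. Without control replicate 2 the median was -0.02.

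Calcium handling genes went both ways. Of 23 measured, 7 rose and 10 fell, also when adjusted over the list alone, and 6 did not pass (camera adjusted p = 0.289; fry adjusted p = 0.00207). Ryr2, the calcium release channel, fell 2.13-fold and its partner gene Jph2 1.66-fold, whereas Slc8a1, the sodium-calcium exchanger, rose by 1.07 on the log2 scale and the T-type channel genes Cacna1h and Cacna1g by 1.67 and 1.23. The list's median was -0.09, and positive on the RPKM scales. Genes of sodium, potassium and pacemaker channels and connexins were more often lower than higher with TMM, with 17 of 29 lower, 3 higher (Kcna4, Kcne1 and Kcnj5) and 9 not past the threshold, or 17 lower and 5 higher adjusted over the list alone. Without mutant replicate 1, 5 were higher. Beyond Hcn2 and Kcnd2, Kcnd3 fell 6.40-fold and Kcnj3 8.16-fold. Exons of Kcnj3 overlap a gene on the opposite strand over 31.1% of their bases. The median of the channel list was -0.49, and -0.01 on log2(RPKM + 0.1), where 10 were higher and 10 lower (camera adjusted p = 8.13e-04, and adjusted p = 0.265 with an estimated correlation).

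**Figure D2:**
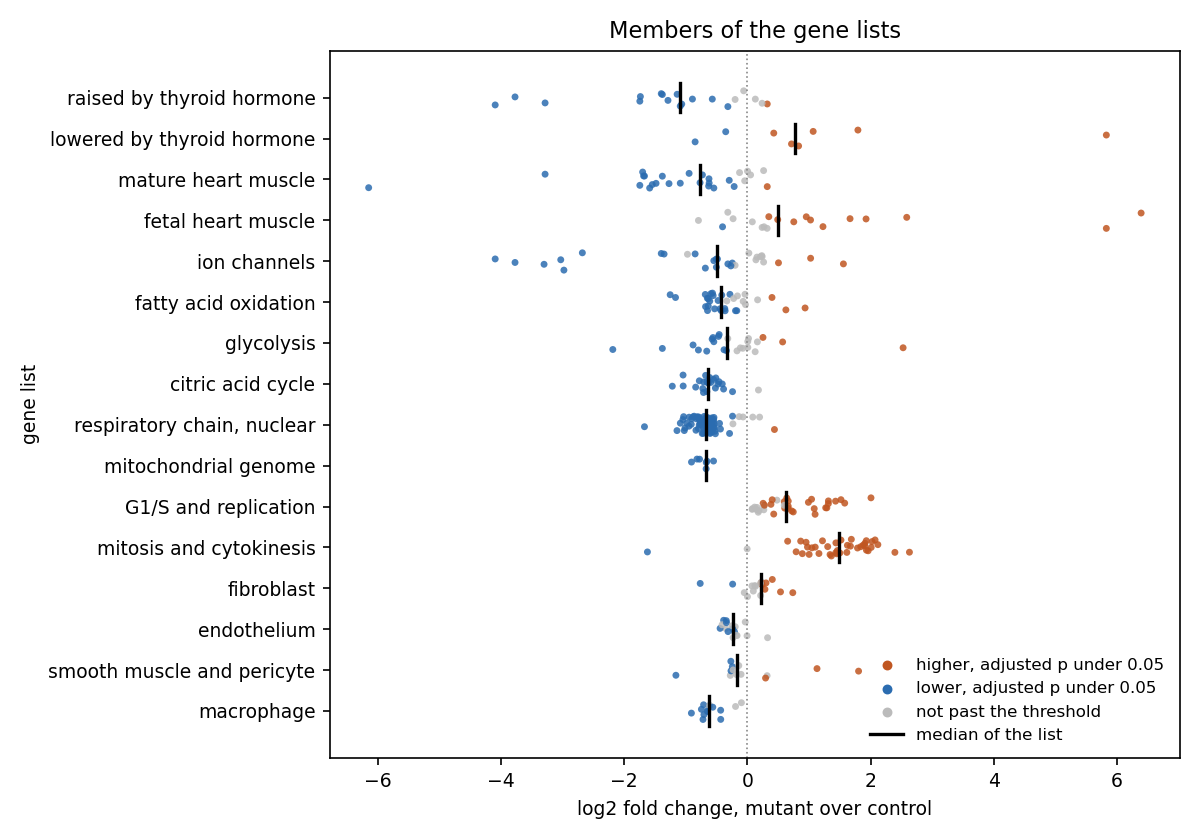
Log2 fold change, mutant over control, of each tested member of 16 gene lists. Each point is a gene, coloured by its edgeR call (orange higher, blue lower, grey not past an adjusted p of 0.05), and black bars are list medians, which run from -1.09 for genes raised by thyroid hormone to 1.48 for mitosis and cytokinesis; on the RPKM scales the endothelium and the smooth muscle and pericyte medians turn positive.

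Genes of mitochondrial energy metabolism fell together. Of 78 measured nuclear genes for subunits of the respiratory chain and ATP synthase, 72 fell, 1 rose (Atpif1, the inhibitor of ATP synthase) and 5 did not pass, or 73 and 1 adjusted over the list alone. Ndufa1 fell 2.21-fold, Ndufs4 2.02-fold and Ndufa5 2.03-fold. The median was -0.68 (camera adjusted p = 3.31e-24, and adjusted p = 0.265 with an estimated correlation). Of the protein-coding genes of the mitochondrial genome, 10 were among the deposited genes and 7 of these passed the filter on low counts. All 7 tested genes fell, also adjusted over the list alone. Among them were mt-Nd2, by 1.87-fold, and mt-Cytb, from 55237 ± 2732 to 32267 ± 2183 CPM (SD, n = 3 each). Their median was -0.67 (camera adjusted p = 1.16e-04, and adjusted p = 0.338 with an estimated correlation). Of 24 genes of pyruvate dehydrogenase and the citric acid cycle, 23 fell, with Sucla2 2.33-fold and Pdhb 2.06-fold lower. The other, Idh2, had a log2 fold change of 0.18 and did not pass the test over all genes, but passed as higher when adjusted over the list alone, where 23 were lower and 1 higher. Their median was -0.64 (camera adjusted p = 3.37e-11, and adjusted p = 0.265 with an estimated correlation). The medians of the nuclear, mitochondrial and citric acid cycle lists stayed negative on log2(RPKM + 0.1), at -0.40, -0.39 and -0.35. The calls of mt-Cytb, mt-Nd2, mt-Nd4 and mt-Co1 were lost on log2(RPKM + 1) without a filter (limma adjusted p up to 0.540).

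Genes of fatty acid and glucose use went both ways, with more lower than higher. Of 32 genes of fatty acid uptake and oxidation, 22 fell, 3 rose and 7 did not pass, or 25 and 4 adjusted over the list alone. Cpt2 of the carnitine shuttle fell 2.24-fold and Acad11 2.38-fold, whereas Acot2 rose 1.92-fold and both forms of the shuttle's first enzyme rose, Cpt1a by 0.63 and Cpt1b by 0.40 on the log2 scale. Another gene on the same strand shares 81.4% of the exon bases of Cpt1b, so its value is uncertain. The median was -0.42, and -0.14 on log2(RPKM + 0.1), where 12 were lower and 6 higher (camera adjusted p = 1.88e-05, and adjusted p = 0.338 with an estimated correlation). Of 24 genes of glucose uptake and glycolysis, 12 fell, 3 rose and 9 did not pass, or 14 and 4 adjusted over the list alone. Hk2, a hexokinase, fell 4.54-fold, the glucose transporter gene Slc2a4 2.60-fold and the muscle enolase gene Eno3 1.84-fold, while Hk1, Eno1 and Aldoc rose. The median was -0.33, and -0.05 on log2(RPKM + 0.1), where 9 were lower and 6 higher (camera adjusted p = 0.00630, and adjusted p = 0.338 with an estimated correlation). Of 18 genes for mitochondrial biogenesis and uncoupling, 9 fell, 1 rose (Esrrg) and 8 did not pass, or 11 and 1 adjusted over the list alone. The call of Esrrg was lost without control replicate 3 or mutant replicate 1. Ucp2 fell 3.33-fold, Ucp3 2.09-fold and Perm1 2.01-fold, and the coactivator gene Ppargc1a had a log2 fold change of -0.06 (adjusted p = 0.814 in edgeR's test). The median of this list was -0.22 and turned positive on the RPKM scales (camera adjusted p = 0.00172, and adjusted p = 0.265 with an estimated correlation).

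Cell cycle genes were higher in mutant hearts. Of 40 measured genes of mitosis and cytokinesis, 38 rose, also when adjusted over the list alone. Mki67, a marker of cycling cells, rose from 6.47 ± 1.44 to 17.6 ± 3.12 CPM (SD, n = 3 each), and Hmmr, Bub1 and Ccna2 rose 6.19-fold, 5.26-fold and 3.89-fold. Cenpa, the histone variant of centromeres, fell 3.08-fold, from 52.5 ± 6.78 to 17.1 ± 1.82 CPM (SD, n = 3 each), and Cenpf had a log2 fold change of -0.00 (adjusted p = 0.993 in edgeR's test). The median was 1.48 (camera adjusted p = 4.60e-16, and adjusted p = 0.265 with an estimated correlation). Of 36 genes of the G1/S transition and DNA replication, 25 rose and 11 did not pass, and 27 were higher adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, rose 4.02-fold, Uhrf1 2.99-fold and the cyclin gene Ccnd2 2.12-fold, to 401 ± 13.7 CPM (SD, n = 3). Their median was 0.62 (camera adjusted p = 5.10e-11, and adjusted p = 0.265 with an estimated correlation). Of 17 inhibitors of the cell cycle and other brakes on heart muscle division, 6 rose, 3 fell and 8 did not pass, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.194; fry adjusted p = 0.00624). On log2(RPKM + 0.1) the median of these brakes was 0.42 against 0.14 with TMM. On that RPKM scale limma called 12 higher, and the 3 falls were not called. With TMM the median was 0.24 without control replicate 2 and 0.23 without control replicate 3. Btg1 rose 1.72-fold, Rbl1 1.61-fold and Meis1 1.52-fold.

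**Figure D3:**
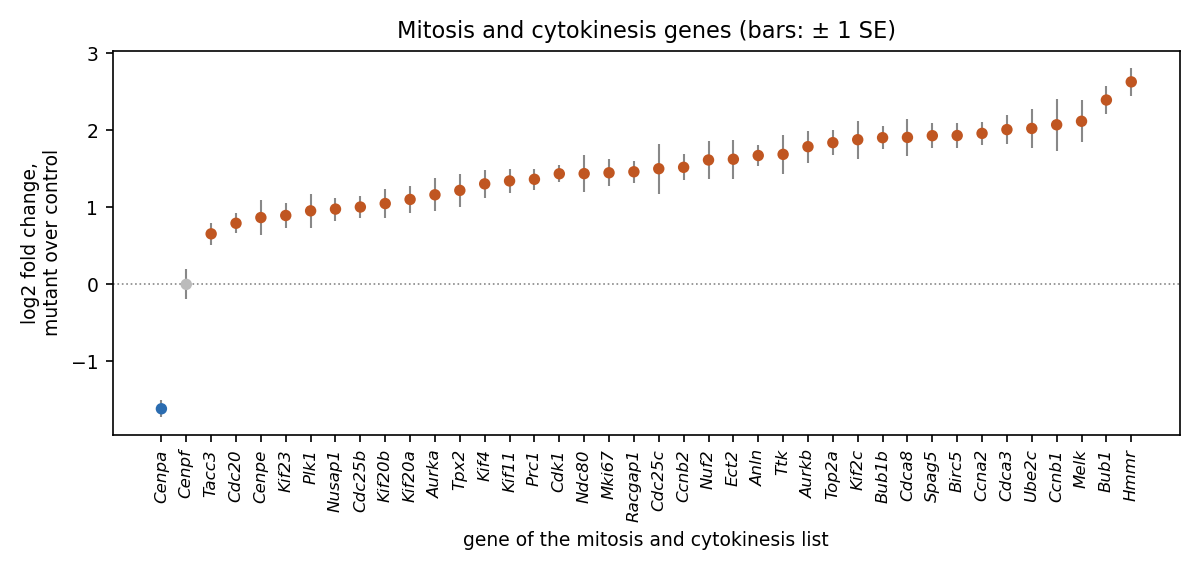
Log2 fold change, mutant over control, of the 40 genes of the mitosis and cytokinesis list, with bars of 1 SE from the edgeR fit. Orange marks the 38 higher genes, blue the lower gene Cenpa at -1.62 and grey Cenpf at -0.00.

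Stress and growth signalling genes were called in both directions. Of 28 genes of antioxidant defence and DNA damage, 6 rose and 10 fell, also adjusted over the list alone, and 12 did not pass (camera adjusted p = 0.187; fry adjusted p = 0.00267). The median of that list turned from -0.13 to 0.14 on log2(RPKM + 0.1), where 10 were higher and 7 lower. The peroxide-removing enzymes Gpx4, Prdx5 and Prdx3 fell 1.80-fold, 1.85-fold and 1.63-fold and Gadd45a 2.59-fold, whereas the repair gene Brca1 rose. Of 21 genes of adrenergic and muscarinic signalling, 7 rose, 4 fell and 10 did not pass, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.546; fry adjusted p = 0.0436). On log2(RPKM + 0.1) 12 of these were higher and 1 lower, with a median of 0.34 against 0.05 with TMM, which became -0.01 without mutant replicate 3. That is close to all genes on that RPKM scale, where the median was 0.27 and 6584 of 12357 were higher. Gnas rose by 0.96 and Prkar1a by 0.48 on the log2 scale, while the muscarinic receptor gene Chrm2 fell 1.47-fold. Of 18 stress targets of Atf4, 6 rose and 4 fell, also adjusted over the list alone, and 8 did not pass (camera adjusted p = 0.554). Psat1 of serine synthesis rose 3.32-fold and Gdf15 2.86-fold, and Chac1 fell by 3.33 on the log2 scale. Of 21 growth factor and Hippo pathway genes, 8 rose and 1 fell, also adjusted over the list alone, and 12 did not pass (camera adjusted p = 0.0846; fry adjusted p = 6.67e-04). On log2(RPKM + 0.1) 17 of 20 were higher and 1 lower, with a median of 0.44 against 0.13. Without control replicate 2, mutant replicate 2 or mutant replicate 3, the number of higher genes in this list was 5, 4 and 5. Igf1r rose from 66.6 to 133 CPM, Igf2r rose 2.08-fold and Fgf1 fell 1.95-fold.

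Markers of other cell types went different ways. Of 14 macrophage genes, 11 fell, also adjusted over the list alone, and 3 did not pass. Csf1r, the receptor on which macrophages depend, fell 1.57-fold and the complement genes C1qa, C1qb and C1qc fell 1.63-fold to 1.68-fold. The median was -0.63, and -0.35 on log2(RPKM + 0.1) (camera adjusted p = 2.56e-05, and adjusted p = 0.141 with an estimated correlation). Of 17 endothelial genes, 7 fell and 10 did not pass, and 11 were lower adjusted over the list alone. Flt1 fell 1.36-fold and Tek 1.24-fold, calls that were lost on the RPKM scales. The endothelial median was -0.24 with TMM and 0.05 on log2(RPKM + 0.1), so its direction depends on the scaling (camera adjusted p = 0.00846, and adjusted p = 0.425 with an estimated correlation). Of 18 fibroblast and matrix genes, 7 rose, 2 fell and 9 did not pass, or 8 and 2 adjusted over the list alone. Without control replicate 2, control replicate 3 or mutant replicate 2, 1 of these was lower. Gsn rose 1.67-fold and Sparc 1.32-fold, and Fap fell 1.70-fold. The fibroblast median was 0.22, and 0.50 on log2(RPKM + 0.1), where 15 were higher and 1 lower (camera adjusted p = 0.0450, and adjusted p = 0.341 with an estimated correlation), a call also lost without control replicate 3 (adjusted p = 0.142), mutant replicate 2 (0.0685) or mutant replicate 3 (0.0729).

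Of 13 smooth muscle and pericyte genes, 3 rose, 4 fell and 6 did not pass, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.546). The lower genes were 2 without control replicate 1, control replicate 2 or mutant replicate 2. Cspg4 rose 2.19-fold and Cnn1 3.50-fold, while Vtn fell 2.23-fold. The median of that list was -0.17, its mean 0.05 and camera's direction negative, and on the RPKM scales the median was positive. Without control replicate 3 it was -0.09. Kcnj8, in the same list, fell by 0.27 on the log2 scale and had no such fall on the RPKM scales. Among 9 atrial genes, 4 rose, 2 fell and 3 did not pass, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.407; fry adjusted p = 0.00546). Without control replicate 3 or mutant replicate 2, 1 atrial gene was lower. Dkk3 rose 2.12-fold, and Bmp10 had 2 counts in all control hearts and 73 in mutant hearts, a ratio of 33.9 with a 95% interval of 9.05 to 285. Among 7 ventricular genes, 2 rose (Hey2, 5.83-fold, and Irx4) and 5 fell, also adjusted over the list alone, with Lrrc10 2.34-fold and Myl3 1.81-fold lower (camera adjusted p = 0.231; fry adjusted p = 0.00510). Without control replicate 3, mutant replicate 1 or mutant replicate 2, 3 ventricular genes were lower. Of 6 skeletal muscle genes, Myh8 rose 10.3-fold to 1.38 CPM, and Tnni2 and Ckm fell 3.25-fold and 1.54-fold, also adjusted over the list alone, and 3 did not pass. The median of the skeletal list was -0.32, its mean 0.06 and camera's direction negative (camera adjusted p = 0.480; fry adjusted p = 0.0448). That median was -0.10 without mutant replicate 2 and -0.17 and -0.21 without control replicate 1 or 3.

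Of 6 genes of epicardium and nerve, 2 fell and 4 did not pass, or 2 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.546). Dbh, the noradrenaline-making enzyme of sympathetic nerves, fell 2.93-fold. Wt1 fell 1.29-fold, a call lost without control replicate 1 (adjusted p = 0.103), control replicate 3 (0.0822), mutant replicate 1 (0.0750) or mutant replicate 3 (0.119). The Wt1 call was also lost on the RPKM scales, with a change of -0.05 on log2(RPKM + 1) (limma adjusted p = 0.587). No gene passed edgeR's test among 8 of lymphocytes and granulocytes or 7 of red blood cells, also adjusted over each list alone (camera adjusted p = 0.168 and 0.546). At an unadjusted p under 0.05 there were 3 and 0 such genes, and DESeq2 and limma-voom called 0 in each list. Camera called the first without control replicate 1 (adjusted p = 0.0223) and the second without mutant replicate 2 (0.0318). The B cell gene Ms4a1 had a log2 fold change of -0.50 (adjusted p = 0.0662 in edgeR's test, 0.0474 without mutant replicate 1 and 0.0303 with offsets for GC content and exon length) and the globin gene Hbb-bs one of -0.43 (0.311), which became 0.00371 without mutant replicate 2. Of 14 immediate early and heat shock genes, Atf3 fell 2.51-fold, also adjusted over the list alone, and 13 did not pass (camera adjusted p = 0.362). Without control replicate 1, 5 of these genes were lower and camera called the list (adjusted p = 0.0223). Of 2 fat genes tested, Thrsp fell 1.48-fold, also adjusted over the list alone. This call was lost without control replicate 3 (adjusted p = 0.0729) or mutant replicate 3 (0.0577). On log2(RPKM + 1) and log2(RPKM + 0.1) it was lost as well (limma adjusted p = 0.168 and 0.169). The 1 tested gene of lung and thymus, Ager, had a log2 fold change of 0.20 (adjusted p = 0.594 in edgeR's test, and 0.0279 without control replicate 3).

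The sex of the pups is not given in the labels. Mutant replicate 1 had 4037 counts of the Y-linked gene Ddx3y, 3799 of Eif2s3y, 1497 of Kdm5d and 1543 of Uty, with 33 of Xist, the RNA of the inactive X chromosome. The other 5 libraries had 26991 to 42057 counts of Xist and at most 1 of each Y-linked gene. Neither Xist nor its antisense gene Tsix passed edgeR's test (adjusted p = 0.805 and 0.755). Without mutant replicate 1, 2661 genes were higher and 2856 lower, and 38 genes of mitosis and cytokinesis were higher.

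Across the 32 lists with enough members, camera with its preset correlation called 16 and fry 25. With an estimated correlation camera called 0, with 4 at an unadjusted p under 0.05, and its adjusted p ranged from 0.141 to 0.425 for the 16.

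The genes Myh6 and Myh7 lie next to each other on the minus strand of chromosome 14, and Mir208b, inside Myh7, and Mhrt, which overlaps it in part, did not follow it. Mir208b, a microRNA gene at 54975700 to 54975776, fell by 3.90 ± 0.25 (SE) on the log2 scale, from 14.2 ± 3.28 to 0.951 ± 0.366 CPM (SD, n = 3 each). Mhrt, a long RNA annotated on the plus strand from 54968678 to 54974349, fell by 2.43 ± 0.17 (SE), and 39.9% of its exon bases overlap exons of Myh7. Mir208a, at 54949060 to 54949142 inside Myh6, had 183 counts in control and 11 in mutant hearts, 17.9-fold lower with a 95% interval of 9.78 to 36.5. These genes were chosen after their values were seen.

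**Figure D4:**
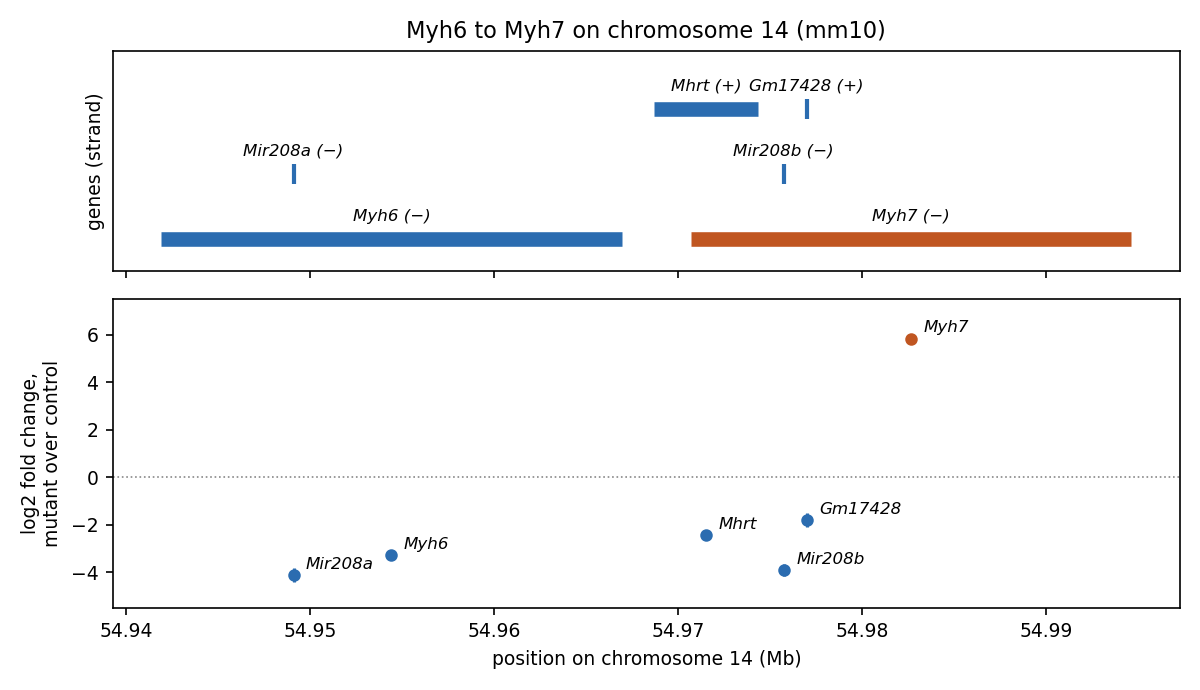
The region from Myh6 to Myh7 on chromosome 14 (mm10, position in Mb), drawn to scale, with annotated strand in brackets. The lower panel gives the log2 fold change, mutant over control, with bars of 1 SE, at the middle of each gene; Myh7 lies at 5.83 and the other 5 genes between -4.13 and -1.81.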

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

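The offsets for GC content and exon length were chosen after the data had been seen, and the other alternatives before. Of the 121 named genes called by edgeR, 118 kept their call and direction in all 15 count-based settings at an adjusted p under 0.05 without a fold threshold, as far as they were tested there. The exceptions were Nppb, Thrsp and Wt1. Most named genes were picked for a small adjusted p or a large change in these same hearts, so this share is higher than for all genes. Without mutant replicate 2, 1997 of the 2688 higher and 2192 of the 2898 lower genes kept their call. With each library left out in turn, 2039 to 2661 genes were higher and 2234 to 2856 lower. With an adjusted p under 0.01, 1751 genes were higher, and glmTreat against a 1.5-fold change called 622 higher and 523 lower and 84 of the 121 named genes, as the stricter tests must give fewer. On the deposited RPKM values limma called 6595 higher and 1083 lower genes with a pseudocount of 1, 6584 and 1077 with 0.1, and 6916 and 1170 without a filter. RPKM lacks the TMM factors, which were 0.905 to 0.908 in control and 1.08 to 1.12 in mutant libraries. Kcnj8 then reversed from -0.27 to 0.0167, 0.0174 and 0.0167, past no threshold, and 107, 107 and 108 named genes kept their call. DESeq2 called 2601 higher and 2738 lower. The number of shifted lists was 16 with camera, 0 with an estimated correlation and 25 with fry, which does not compare a list with other genes. The GC and length offsets gave 3156 higher and 3278 lower genes, added a call for Ms4a1 (adjusted p = 0.0303) and ended the call of the fibroblast list (camera adjusted p = 0.0835, against 0.0450 without them, and 0.0685 to 0.142 without each of the 3 libraries whose removal also ended it). The cause was not tested. The depth, 43314706 to 62095277 counts, limits genes with few counts, such as Bmp10.

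With the replicate number as a block, 3090 genes were higher and 3229 lower. Same-numbered hearts had correlations of their deviations from the group means of 0.260, -0.023 and 0.178 across 12644 genes. The values 0.260 and 0.178 were the highest of all pairs across groups, but control replicate 2 correlated best with mutant replicate 3 (0.087). Whether the numbers pair the hearts stays open. The block added calls for Hbb-bs (adjusted p = 0.0143), Hba-a1 (0.0474) and the growth factor and Hippo list (0.0441), and changed no other call of a named gene or list.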

Other observations

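All tests here were chosen after the data had been seen, except the splits of the hearts, the count without mutant replicate 1 and the test of Gm17428. The 10 gene families described next, from the mitochondrial ribosome to the histones, were picked after the largest changes were known. Their tests describe these hearts and are not independent evidence.

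Transcripts of the mitochondrial ribosome and of amino acid breakdown fell along with those of the respiratory chain. Of 76 proteins of the mitochondrial ribosome, 67 fell and 9 did not pass by edgeR's test, with a median log2 fold change of -0.41 (camera adjusted p = 1.20e-15, and adjusted p = 0.178 with an estimated correlation). Of 77 proteins of the cytosolic ribosome, 73 did not pass the test and the median was 0.02 (camera adjusted p = 0.549). Their levels ranged widely, and low ones such as Rps6 (0.400 CPM in control hearts, SE 0.30) and Rpl19 (0.493 CPM, SE 0.26) were weakly measured. Others, such as Rpl4 at 428 CPM, were well counted. The exception in the cytosolic family was Rpl3l, the form of a ribosomal protein made in striated muscle, which fell by 3.09 on the log2 scale. Rps2, Rpl22 and Rpl3 had smaller changes. Of 19 genes for the breakdown of branched-chain amino acids, 17 fell and 2 did not pass, with a median of -0.65 (camera adjusted p = 1.67e-09, and adjusted p = 0.0742 with an estimated correlation). Of 13 genes of coenzyme Q, 11 fell and 1 (Coq8b) rose, with a median of -0.64 (camera adjusted p = 1.42e-05, and adjusted p = 0.170 with an estimated correlation), and Coq10a fell 3.78-fold. Oxct1, the entry enzyme of ketone body use, fell 3.98-fold, one of 3 of 4 genes of that route that fell (camera adjusted p = 0.0107, and adjusted p = 0.267 with an estimated correlation). These medians were also negative on log2(RPKM + 0.1), at -0.13 for the mitochondrial ribosome, -0.37 for branched-chain amino acids, -0.35 for coenzyme Q and -0.27 for ketone use.

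Of 39 genes with the name of a proteasome subunit, 33 fell and 6 did not pass, with a median of -0.37, or -0.09 on log2(RPKM + 0.1). They were matched by name, and Psmc3ip among them, at 0.35, is not a subunit. Theirs was the one family call that held with an estimated correlation (camera adjusted p = 7.48e-09, and adjusted p = 0.0486 with an estimated correlation). The adjustment for each family was over the 10 families alone. The proteasome value therefore cannot be set against those of the 32 fixed lists, and lies close to the threshold. Of 22 translocases of the mitochondrial membranes, 12 fell and 1 rose, with a median of -0.28 that became 0.01 on log2(RPKM + 0.1) (camera adjusted p = 3.40e-04, and adjusted p = 0.267 with an estimated correlation). Of 43 mitochondrial carriers, 18 fell and 2 rose, with a median of -0.19 that became 0.08 on that scale (camera adjusted p = 0.00209, and adjusted p = 0.167 with an estimated correlation). Tubulins went both ways, with 5 of 13 higher and 4 lower (camera adjusted p = 0.655). Tuba8 fell by 4.04 on the log2 scale while Tubb2b rose by 3.63. Of 9 histone genes, 3 rose and 2 fell (camera adjusted p = 0.655).

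The 6 hearts can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. In each of the other 9 splits edgeR called 0 genes higher and 0 lower, with 57 to 829 genes at an unadjusted p under 0.05. The real split gave 2688 and 2898, so that 1 of the 10 splits gave as many in each direction. The other splits mix both genotypes in each group, so the genotype difference counts there as spread between hearts. Few calls are likely for that reason alone, and these splits do not show what hearts without a difference would give. Camera with its preset correlation called 16 lists in the real split and up to 14 in the others.

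Mitosis genes rose in a 14-day-old heart, when most heart muscle cells of the mouse have left the cell cycle. More fibroblasts, endothelial cells, smooth muscle cells and pericytes, or macrophages, with an unchanged share of dividing cells, would not account for the whole rise. This holds only if the marker genes of these cells follow their number. With TMM the highest upper 95% bootstrap bound of the medians of these 4 lists was 0.2959, under the mitosis median of 1.48. All bootstrap bounds here come from resampling the genes of a list, not the hearts, so they do not measure spread between hearts. On log2(RPKM + 0.1) the highest of the 4 medians was 0.50, for the fibroblast list (5 of the 62 tested members are also in other lists). These medians can move with the number of such cells or with the expression of the markers in each cell. They cannot tell whether a larger share of these cells divided. The rise did not rest on the library with Y-linked counts, since 38 members were higher without it. Other scalings, RPKM included, shifted the median of all genes by at most 0.2691, against a lower bootstrap bound of 1.33 for the mitosis median, which was 1.47 on log2(RPKM + 0.1) and 0.66 on log2(RPKM + 1) over the 25 members past the RPKM filter, so scaling is not the whole cause. Cell types outside these 4 lists were not weighed and which cells carry these transcripts stays open, and a candidate explanation is that heart muscle cells with blocked hormone signalling divide for longer, which whole-heart counts cannot test.

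Cenpa fell while 38 other genes of its list rose. Reads running on from Slc35f6, its upstream neighbour on the same strand of chromosome 5, would fall as Slc35f6 does, but Slc35f6 fell by 0.69 and the difference was 0.9265 ± 0.131 (SE), which argues against constant run-on as the whole cause. In control hearts Cenpa had a mean deposited RPKM of 8.07, the highest of the 40 members, and 31.73 times the median of the others. A candidate explanation is a pool of Cenpa transcripts outside dividing cells in the control hearts that is lost in the mutant hearts. An unannotated transcript over this gene, or run-on whose efficiency differs between groups, was not tested.

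Mir208b, inside Myh7, and Mhrt, which lies partly outside it, fell while Myh7 rose 56.7-fold. If their counts were reads of the Myh7 primary transcript, they would have risen, and the highest upper 95% bound of their log2 fold changes was -2.0979. RNA from the opposite strand of Myh7 that moves with Myh6 is consistent with another gene model there, Gm17428 on the plus strand, which fell by 1.81 (-1.8110, edgeR adjusted p = 0.00114). Gm29015 and Gm31251, gene models whose exons also overlap those of Myh7 on the opposite strand, were not part of this comparison. As the kit does not mark strand, the strand of the reads of Mir208b, Mhrt and Gm17428 may not be known from the counts. RNA from the opposite strand of Myh7 therefore stays a hypothesis. These libraries do not measure mature microRNAs.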
